A study of Mus musculus with 153 samples.

How the data were processed

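The series holds RNA sequencing of mouse dorsal hippocampus from 3 driver lines, as ribosome-bound RNA pulled down from the marked neurons and as the total lysate, in mice kept in the home cage, placed in a new context, or shocked in it, in sets labelled 15 min and 60 min. Per the labels' protocols, RNA was isolated with the RNeasy Mini kit as polyA RNA and libraries were made with the Nextera XT kit, which does not mark the strand, so reads of overlapping and antisense genes cannot be told apart. Groups, fractions and replicate numbers were taken from the labels, which describe 153 samples.

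The deposited values are read counts per gene symbol, not normalised, in 6 tables, each with both fractions of 1 line and 1 time set. Per the submitters' processing notes, STAR 2.7.7a, featureCounts, DESeq2 and the mouse genome build GRCm38 were used, with no role or order given, and the annotation behind the counts is not given in the sources used here. How reads that fit several genes were treated is not given either, so values of genes with near-identical copies, such as ribosomal protein genes and their pseudogenes, are uncertain. The tables listed 23366 genes in the Camk2a set at 15 min and 24391 in the others, with 0 mitochondrially encoded genes, so no list of those could be tested. Of the 151 count columns used, 3 could be matched to a group but not to a sample, because a column name matched no label or stood on 2 columns. They entered the fits as replicates without a number. For 2 samples of the labels no column was matched, and they are not analysed here. No other column of single samples was left unused.

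Every pair of libraries within a group was compared by a chi-square statistic over genes, and none agreed within sampling noise (smallest reduced value 20.6). Total counts per library ran from 9043042 to 397228206. Among purified contrasts the median SE of a log2 fold change was largest in the Sst set at 15 min, 0.48 to 0.54. Counts cover molecules and their amplified copies alike, since no molecular identifiers were used in the counting as far as the sources say.

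Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, estimateDisp, glmQLFit with robust estimation, glmQLFTest) with Benjamini-Hochberg adjustment over the genes of a contrast and a threshold of 0.05. The purified libraries of 1 table were fitted together over the 3 conditions. Lysates of the 3 lines of a time set were fitted together with line as a covariate. Enrichment of the purified fraction over the lysate and the difference of their shock responses were fitted over all libraries of a table. Differences between lines used all purified libraries of a time set, and differences between time sets all purified libraries of a line. In both of these the line or the set is confounded with any difference between tables. A standard error is the log2 fold change divided by the square root of the test's F value. CPM are counts-per-million values over all counts listed in a library, and log2 CPM for scores had a prior count of 2. The sexes of the animals were called from Y-linked genes, as male above 5 CPM.

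Before the data were examined, 36 gene lists were fixed: 8 response lists, 6 pathway lists, 6 neuronal lists, 15 lists of cell class markers and a sex-linked list. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, again with the correlation estimated, and with fry in its directional and mixed forms. Adjustment ran over the 19 testable response, pathway and neuronal lists of a contrast, and separately over the cell class lists. Adjusted p-values of lists in the text are those with an estimated correlation unless they are called camera's. Marker scores are means of log2 CPM over lists. The own-class score is the mean of the line's marker lists minus that of the other classes. Each library's GC slope is the trend of its log2 CPM deviations over GC content, with GC content and exon lengths from GENCODE release M21 on GRCm38, matched by symbol for 93.8% to 96.2% of tested genes per table. Coordinates come from the same annotation.

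Genes in the text were named by a rule fixed at the same time. For shock against home cage in purified libraries these were the 6 risen and 6 fallen genes with the smallest p whose groups did not overlap, for other condition contrasts 4 and 4 by smallest p, and for differences between responses 3 and 3. For each list they were up to 4 members past the threshold, or otherwise the member with the smallest p. Fos, Arc, Npas4, Egr1, Bdnf, Camk2a, Pvalb and Sst were always open to naming. Gene models without an established symbol and sex-linked genes were counted and not named, and a gene that the rule allowed is not reported here. Which of the genes that the rule allows were printed, and a few further list members given as examples, was chosen after their values were seen.

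Alternatives fixed at the same time were DESeq2 1.42.0 in place of edgeR, DESeq2's size factors in edgeR (RLE), no filter on low counts, the replicate number as a block, each library left out in turn, each line left out of the lysate fits, and a score of non-neuronal markers as a covariate. Alternatives chosen after the data had been seen were per-library offsets from loess trends (span 0.5) on GC content and exon length, the own-class score or sex as a covariate, and fits without libraries of low own-class score (less than 1 log2 unit above the lysates), without libraries of over 250000000 counts, and without part of the Pvalb shock libraries at 60 min. An adjusted p that DESeq2 left out stayed out. Each contrast was also refitted after reassigning the same libraries to groups of the same sizes, over at most 100 splits for purified contrasts, 25 for differences between lines and 40 for all others, the real one included. The last 2 of these numbers were lowered for run time alone after first counts for part of the contrasts had been seen.

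Only gene calls and camera were tested on counts simulated from means and library sizes of the samples, with some genes changed by known folds. The test recovered 36.8% and 58.6% of genes changed 2-fold and 4-fold for purified Camk2a libraries at 60 min. It recovered 44.9% and 76.8% for Pvalb at 60 min and 1.03% and 23.7% for Sst at 15 min. Lysates at 15 min gave 78.0% and 89.0%. No changed gene was called in the wrong direction, and 0 to 8 unchanged ones per comparison. Splits of real libraries called up to 6112 genes, so these rates hold for simulated counts only. Figures were drawn with matplotlib 3.10.9.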

Results

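RNA was measured in the dorsal hippocampus of mice in which a Cre driver marks 1 of 3 neuron classes. Camk2a-Cre marks excitatory neurons, Pvalb-Cre marks parvalbumin interneurons and Sst-Cre marks somatostatin interneurons, and each driver was combined with a floxed TRAP allele. TRAP, translating ribosome affinity purification, tags a ribosomal protein in the marked cells so that their ribosomes can be pulled out of the tissue with the mRNA they carry. From each line the ribosome-bound RNA (purified fraction) and the total lysate, which holds RNA of every cell of the tissue, were sequenced as polyA RNA. Mice had stayed in the home cage, had been placed in a new context without a shock (box), or had been shocked in that context (shock), in sets labelled 15 min and 60 min. The 151 libraries fell into 36 groups of 3 to 6, which the submitters call biological replicates, so p-values measure the spread between these samples. Total counts ran from 9043042 in a purified Camk2a library to 397228206 in a purified Sst library. At 15 and 60 min the medians were 71552506 and 55390174 in purified Camk2a, 79985570 and 115057360 in purified Pvalb, and 101451694 and 70408556 in purified Sst libraries. Lysate medians lay between 27861790 and 78097188. Below, log2 fold changes stand with the standard error of the fit (SE), CPM (counts-per-million) with the standard deviation over n libraries (SD), and adjusted p-values are those of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

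The purified fraction was first set against the lysate of the same table to see which cell classes it held, averaged over the 3 conditions. In Camk2a libraries at 60 min all 12 pyramidal neuron markers were higher than in the lysate, with a median log2 fold of 1.18, and all 12 passed the test. Nrgn, a calmodulin-binding protein of excitatory neurons, reached 5752 ± 1209 CPM against 1662 ± 261 (SD, n = 12 each; 2.11 ± 0.13 SE, adjusted p = 1.31e-12). Glia were depleted there: the medians were -3.81 for astrocyte, -3.58 for oligodendrocyte and -3.38 for microglia markers, all members lower, and -2.35 for general GABA neuron markers. The GABA neuron result did not pass with an estimated correlation between genes (adjusted p = 0.183), whereas the glial and pyramidal lists did. In Pvalb libraries at 60 min the parvalbumin neuron list had a median of 4.41 with 7 of 7 members up, and the GABA neuron list 2.66 with 12 of 12 up. Pvalb itself, the calcium buffer that names the class (chromosome 15, 78191114 to 78206400, GRCm38), stood 5.75 ± 0.13 above the lysate (SE; n = 16 each). The medians of the matching lists at 15 min were 0.96 for Camk2a and 4.07 for Pvalb. In Sst libraries the somatostatin neuron list had a median of 3.04 at 15 min (1.95 with the replicate number as a block) and 2.42 at 60 min, 7 of 7 members up in both, but neither list passed with an estimated correlation (adjusted p = 0.535 and 0.378).

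The purified Sst libraries differed between conditions in how much Sst cell RNA they held. A score of each line's own markers minus those of the other classes, taken over the mean of the lysates, was 4.40 ± 0.66 log2 units in home cage (SD, n = 4) at 15 min. It was 2.95 ± 3.10 in box (n = 3) and 0.41 ± 2.87 in shock libraries (n = 5). At 60 min it was 2.48 ± 1.94 in home cage (n = 5), 3.27 ± 1.31 in box (n = 4) and -0.27 ± 0.22 in shock libraries (n = 4), where the single shock libraries lay between -0.51 and 0.01. Low libraries were found in other groups too, home cage replicate 3 at 60 min with -0.24 and box replicate 2 at 15 min with -0.62. In the Camk2a and Pvalb sets every group mean lay between 3.73 and 4.73.

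**Figure D1:**
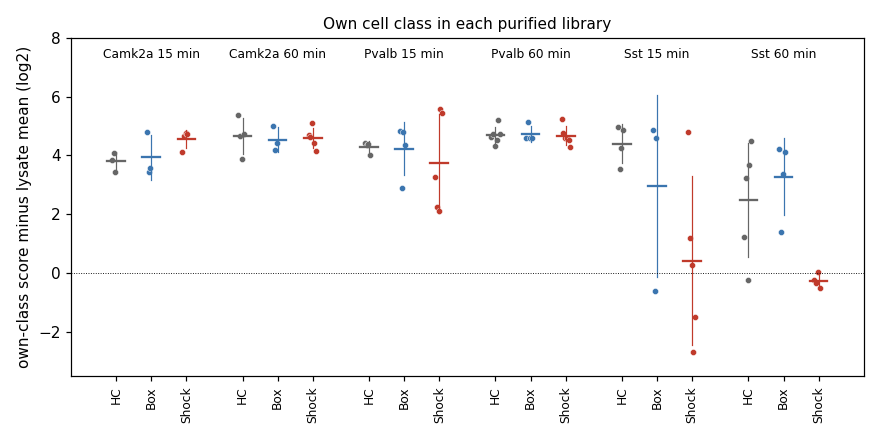
Own-class score of every purified library (y axis, log2 units over the mean of the lysates of the same table) by line, time set and condition; points are libraries and bars the mean with the SD. The Sst shock libraries at 60 min lie between -0.51 and 0.01, and the Pvalb groups at 60 min have means of 4.67 to 4.73.

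In total lysates of the 15 min set, shock raised transcripts of neuronal activity. Of 15588 genes tested over the 3 lines together, 20 rose and 0 fell against home cage (edgeR; 896 at an unadjusted p under 0.05 in both directions together, 68 called by DESeq2). Nr4a1, an activity-induced nuclear receptor (chromosome 15, 101254269 to 101274795), stood at 118 ± 36.3 CPM after shock and 45.5 ± 12.7 in home cage (SD, n = 14 and 10; 1.32 ± 0.14 SE, adjusted p = 7.85e-07). Arc, a synaptic immediate early gene (chromosome 15, 74669083 to 74672570), rose by 1.59 ± 0.19 from 175 ± 70.0 to 528 ± 200 CPM (adjusted p = 7.53e-06). The transcription factor genes Egr2 (3.04 ± 0.45), Fos (2.10 ± 0.35) and Egr1 (0.79 ± 0.15) rose too, with adjusted p = 0.000585, 0.00284 and 0.0147, as did Cyr61, a secreted matrix protein (1.59 ± 0.30, adjusted p = 0.0102). Of the list of rapid activity genes, 27 of 29 measured members were higher, 10 rose, and 18 rose when adjusted over the list alone (camera adjusted p = 2.03e-43, and 3.96e-05 with an estimated correlation). The MAP kinase phosphatases Dusp1 (1.20 ± 0.20) and Dusp5 (0.62 ± 0.12) were the 2 of 13 members of the MAP kinase feedback list that rose, and 4 rose adjusted over the list alone (adjusted p = 0.102 with an estimated correlation). The glucocorticoid list held 2 risen genes of 20, the kinase gene Sgk1 (0.84 ± 0.16) and the NF-kappaB inhibitor Nfkbia (0.54 ± 0.09), and 3 adjusted over the list alone (adjusted p = 0.00955 with an estimated correlation). Among 14 heat shock genes Dnajb1 rose (0.63 ± 0.14, adjusted p = 0.0429), 1 also over the list alone. Npas4 (22.3 ± 45.4 against 4.60 ± 3.38 CPM, adjusted p = 0.432) and Bdnf (-0.14 ± 0.15) did not pass. A single Camk2a lysate, shock replicate 4, held 462 CPM of Fos where the other 3 of its group held 37.2 to 46.6. Without the Pvalb line or without the Sst line 2 genes were called, and without the Camk2a line 17.

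The new context alone was compared with home cage. Nr4a1 (0.97 ± 0.15 SE; 90.8 ± 23.2 against 45.5 ± 12.7 CPM, SD, n = 10 each; adjusted p = 0.00224) and Arc (1.23 ± 0.20; 401 ± 147 against 175 ± 70.0 CPM; adjusted p = 0.00418) rose in lysates at 15 min. No other gene passed (edgeR; 529 at an unadjusted p under 0.05, 61 by DESeq2). The rapid activity list was higher for 27 of 29 members with a median of 0.61, and 13 rose adjusted over the list alone (adjusted p = 0.00136 with an estimated correlation). Fos stood at 45.8 ± 10.6 CPM and 1.43 ± 0.36 above home cage without passing (adjusted p = 0.445). Without the Pvalb line or without the Sst line 0 genes passed, and without the Camk2a line 7 did. Shock and box lysates differed in 0 genes (edgeR; 245 at an unadjusted p under 0.05, 17 by DESeq2), with Arc at 0.36 ± 0.18 and Fos at 0.67 ± 0.33. The glucocorticoid list was higher after shock than after box for 16 of 20 members, median 0.13, none passing singly even over the list alone (adjusted p = 0.0369 with an estimated correlation). The rapid activity list, 26 of 29 higher, had adjusted p = 0.190.

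At 60 min no single gene passed in the lysates. The counts were 0 for shock against home cage (edgeR; 536 at an unadjusted p under 0.05, 22 by DESeq2), 0 for box against home cage (205 and 16) and 0 for shock against box (145 and 19), over 16272 genes. The lists still moved together: 19 of 20 glucocorticoid genes were higher after shock than in home cage (median 0.21, adjusted p = 0.00167 with an estimated correlation). So were 25 of 29 rapid activity genes (median 0.18, adjusted p = 0.0208) and 11 of 13 MAP kinase feedback genes (median 0.13, adjusted p = 0.0208). Over the list alone 2 glucocorticoid and 2 rapid activity genes rose. Sgk1 held 305 against 170 CPM (0.87 ± 0.17 SE, adjusted p = 0.137), Egr2 9.37 against 4.65 (1.13 ± 0.24, adjusted p = 0.225) and Fos 29.6 against 21.2 (0.55 ± 0.13, adjusted p = 0.478). Arc stood at 340 CPM after shock and 331 in home cage. Box lysates had 24 of 29 rapid activity genes higher than home cage (adjusted p = 0.0126 with an estimated correlation), 16 of 20 glucocorticoid genes (0.0126) and 10 of 13 MAP kinase feedback genes (0.0190). Endothelial markers were lower after shock than after box, 9 of 11 members, with a median of -0.18 (adjusted p = 0.0437 with an estimated correlation). GC and length offsets gave 2 genes and leaving out the 3 Sst lysates of over 250000000 counts gave 1 gene for shock against home cage.

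**Figure D2:**
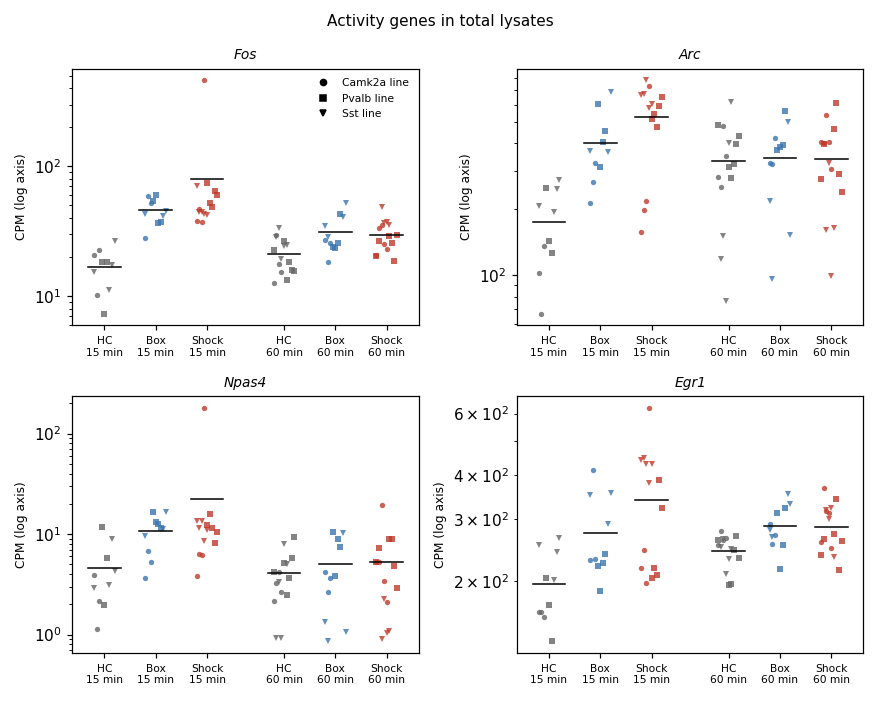
CPM of activity genes in every total lysate (y axis, log scale) by time set and condition; points are libraries, with a marker shape for each line and a colour for each condition, and black lines are the means over libraries. Arc lies at a mean of 175 CPM in home cage, 401 in box and 528 in shock lysates at 15 min, and at 331 in home cage and 340 in shock lysates at 60 min.

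In the purified Camk2a fraction at 15 min no gene passed. The counts were 0 for shock against home cage (edgeR; 1288 at an unadjusted p under 0.05, 81 by DESeq2), 0 for box against home cage (397 and 40) and 0 for shock against box (1336 and 37). Leaving out shock replicate 1 gave 3 for shock against home cage. Means of activity genes were higher: Fos 120 ± 156 against 14.9 ± 5.03 CPM (SD, n = 4 and 3; 2.96 ± 0.81 SE, adjusted p = 0.502). Arc stood at 305 ± 168 against 76.2 ± 20.9 (adjusted p = 0.407) and Npas4 at 23.5 ± 39.9 against 0.75 ± 0.29 (adjusted p = 0.502). Shock replicate 4 held 353 CPM of Fos and 83.4 of Npas4, and the other 3 at most 44.0 and 4.58. Of 29 rapid activity genes 24 were higher, 12 rose and 1 fell adjusted over the list alone (list adjusted p = 0.477). In box against home cage 20 of 24 delayed activity genes were higher, median 0.32 (adjusted p = 0.0341 with an estimated correlation). In simulated data of this size the test recovered 65.3% of genes changed 4-fold and 10.5% of those changed 2-fold.

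At 60 min after shock the purified Camk2a fraction differed from home cage in 338 genes, 244 higher and 94 lower, of 14673 tested (edgeR; DESeq2 called 2133), all at adjusted p between 0.0475 and 0.05. Of all genes tested, 1428 (9.73%) had no overlap between the 5 shock and 4 home cage libraries, which chance gives for 1.59%, though genes are not independent of each other. Those that rose included 3 rapid activity genes of 29, 5 over the list alone: Egr3 (0.92 ± 0.23), Egr1 (0.81 ± 0.18, 448 ± 125 against 264 ± 22.1 CPM) and Fbxo33, a ubiquitin ligase subunit (0.81 ± 0.20). That list had adjusted p = 0.654. Of 24 delayed activity genes Tiparp rose (1.31 ± 0.31), and 6 over the list alone (adjusted p = 0.101 with an estimated correlation). Glutamate receptor genes Grm5 (0.83 ± 0.19), Gria2 (0.67 ± 0.15; 775 ± 85.6 against 506 ± 29.6 CPM) and Gria3 (0.65 ± 0.16) rose, 3 of 24 postsynaptic genes, 5 over the list alone. Of 16 GABA receptor genes 12 were higher, median 0.49. Gabra2 rose (0.87 ± 0.20), and over the list alone 10 rose and 1 fell (adjusted p = 0.275 with an estimated correlation). The potassium channel genes Kcnab1 (0.91 ± 0.21), Kcnd2 (0.88 ± 0.20) and Kcnn2 (0.87 ± 0.21) rose, 3 of 27. The chaperone genes Hspa1b (0.95 ± 0.24), Dnaja1 (0.89 ± 0.23), Pdia3 (0.77 ± 0.20) and Hsp90b1 (0.59 ± 0.14) rose, 2 of 14 heat shock and 2 of 16 endoplasmic reticulum chaperone genes. By rank the leading risen genes were Arhgap12 (1.27 ± 0.21; 264 ± 76.3 against 114 ± 17.8 CPM), Zfp938, Seh1l, Prkab2, a subunit of the energy-sensing kinase AMPK, Cdk17 and Flrt2. Those that fell were Rhbdd3 (chromosome 11, 5098926 to 5106093; -1.29 ± 0.21, 17.6 ± 4.17 against 44.3 ± 5.22 CPM), Fbxo2, Ehbp1l1, Mapk11, Ppm1m and Azin2, and of the synaptic vesicle list Stx1a fell (-0.71 ± 0.18), 1 of 23. Fos, Arc, Npas4 and Bdnf did not pass (adjusted p = 0.345, 0.996, 0.334 and 0.180). Box against home cage gave 0 genes (edgeR; 294 at an unadjusted p under 0.05, 16 by DESeq2) and shock against box 0 (2214 and 105). The groups also differed in GC slope, the log2 change of a library's values per 10 percentage points of GC, which was -0.25 ± 0.23 in shock and 0.22 ± 0.10 in home cage libraries. They differed in sex too, 1 male of 5 against 3 males of 4 by Y-linked genes. The 338 calls became 181 with DESeq2's size factors, 1 with GC and length offsets (Gria2 then stood at -0.044), and 0 with sex, the non-neuronal score or the own-class score as a covariate. Leaving out any 1 of home cage replicates 1 to 4 or shock replicates 1, 4 or 5 gave 0 calls, leaving out shock replicate 2 gave 957 and shock replicate 3 gave 1858.

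In the purified Pvalb fraction at 15 min the counts were 0 for shock against home cage (edgeR; 2413 at an unadjusted p under 0.05, 390 by DESeq2), 0 for box against home cage (260 and 67) and 0 for shock against box (2411 and 530). Arc stood at 185 ± 106 CPM against 33.6 ± 15.6 (SD, n = 5 and 4; 2.32 ± 0.41 SE, adjusted p = 0.192). Fos stood at 54.6 ± 12 against 24.1 ± 7.22 (1.06 ± 0.28, adjusted p = 0.239) and Egr1 at 95.0 ± 16.8 against 48.0 ± 10.4 (adjusted p = 0.239). Of the cell class markers 10 of 12 pyramidal genes and 2 of 12 GABA neuron genes had higher means after shock, with medians of 0.37 and -0.50, and neither list passed (adjusted p = 0.881 for both with an estimated correlation). Own-class scores ran from 2.10 to 5.58 in shock and from 4.02 to 4.41 in home cage libraries. Of 29 rapid activity genes 24 were higher after shock, 9 rose and 1 fell adjusted over the list alone (list adjusted p = 0.359). Calls for shock against home cage numbered 6 with the non-neuronal score as a covariate, 3 with the own-class score and 6 without shock replicate 5.

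At 60 min 5655 of 16135 genes differed between shocked and home cage mice in the purified Pvalb fraction, 3179 higher and 2476 lower (edgeR; DESeq2 called 6556). The 6 shock and 6 home cage libraries did not overlap in 1705 (10.6%) of all genes tested, where chance gives 0.216%. Genes of the protein synthesis machinery were among those that rose: 44 of 80 ribosomal protein genes rose and 4 fell, led by Rpl34 (1.63 ± 0.29), Rpl36 (1.53 ± 0.23, 98.8 ± 29.0 against 34.0 ± 11.2 CPM), Rpl18 (1.51 ± 0.23) and Rps4l (1.47 ± 0.23). Of 64 translation factor genes 19 rose, among them Eef2 (1.21 ± 0.19, 702 ± 204 against 302 ± 43.4 CPM) and Eif6, and 13 fell. Nuclear genes of oxidative phosphorylation rose in 38 of 76 cases and fell in 5, with Ndufs7 (1.45 ± 0.23), Atp5d (1.39 ± 0.22) and Uqcr11 (1.31 ± 0.19). Of 20 genes of the ATF4 stress response 11 rose, among them Sesn2 (1.38 ± 0.25), Cebpb (1.31 ± 0.26) and Ddit3 (1.16 ± 0.29), and 2 fell. With an estimated correlation none of these lists passed (adjusted p = 0.730 for ribosomal and for oxidative phosphorylation genes, 0.820 for the ATF4 list, 0.874 for translation factors). GABA receptor genes went both ways, 3 up and 8 down of 16, with Gabrd higher (1.16 ± 0.20) and Gabrb2 (-0.96 ± 0.27), Gabra2 (-0.90 ± 0.30) and Gabra4 (-0.77 ± 0.22) lower (adjusted p = 0.730 with an estimated correlation). The activity genes Arc (1.16 ± 0.27, 123 ± 41.3 against 54.8 ± 14.3 CPM), Gadd45g (1.33 ± 0.27) and Egr4 (1.15 ± 0.29) rose, 7 rapid activity genes in all with 3 that fell. Of the others Fos (adjusted p = 0.339), Egr1 (0.647) and Npas4 (0.874) did not pass. Sst (1.03 ± 0.21; 692 ± 143 against 334 ± 101 CPM) and Cort (1.34 ± 0.28), peptide genes of somatostatin neurons, rose, and Pvalb stood at 971 ± 124 against 775 ± 97.4 CPM (adjusted p = 0.0661). By rank the leading genes were Sh3bp4 (chromosome 1, 89070415 to 89155068; 2.16 ± 0.28), Selm, Rpp21, Tysnd1, Dlgap3 and Ccdc124 among the risen, and Samd8 (-1.27 ± 0.17), Trmt6, Rbpj, Asah1, B3galt1 and Ppp6c among the fallen, all with adjusted p = 0.000594. GC slope moved with the condition: it was 0.40 ± 0.38 in shock libraries and -0.35 ± 0.08 in home cage, and shock replicates 3 to 6 had 0.56 to 0.73 while replicates 1 and 2 had -0.07 and -0.09. With GC and length offsets 2002 genes were called, 1438 higher and 564 lower, 1588 of them shared with the 5655 (Egr4 then stood at -0.19), and with shock replicates 3 to 6 left out 0 were. Box against home cage gave 0 genes (edgeR; 1829 at an unadjusted p under 0.05, 42 by DESeq2), 404 without shock replicates 1 and 2 in the shared fit, and shock against box 0 (3306 and 653), the latter 1419 without shock replicate 2, 5014 without shock replicates 1 and 2, and 281 with the non-neuronal score as a covariate.

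**Figure D3:**
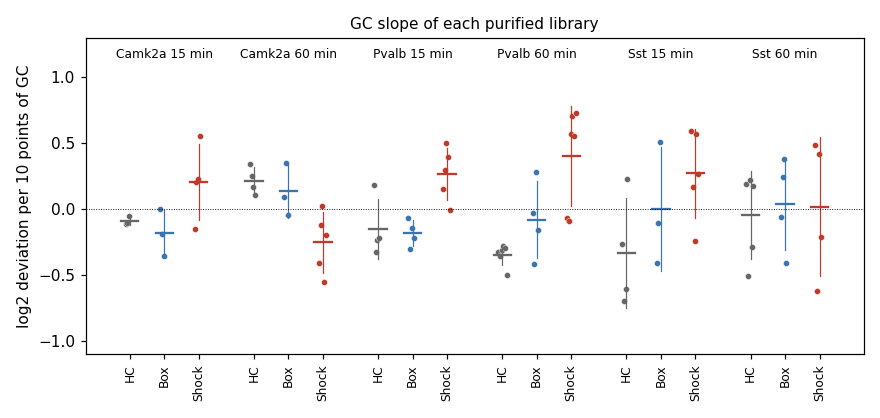
GC slope of every purified library (y axis, log2 change per 10 percentage points of GC content) by line, time set and condition; points are libraries and bars the mean with the SD. In the Pvalb set at 60 min the shock group has a mean of 0.40 and the home cage group -0.35; in the Camk2a set at 60 min the means are -0.25 and 0.22.

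In the purified Sst fraction at 15 min shock libraries differed from home cage in 194 of 16046 genes, 178 higher and 16 lower (edgeR; DESeq2 called 1855). Of all genes tested, 1230 (7.67%) had no overlap between the 5 and 4 libraries (1.59% by chance). Microglia genes led: 12 of 12 were higher with a median of 5.11, 10 rose, and 12 did so over the list alone (adjusted p = 0.277 with an estimated correlation). The complement genes C1qa (chromosome 4, 136895917 to 136898803; 5.89 ± 1.02, 396 ± 264 against 6.04 ± 1.72 CPM) and C1qb, the receptor gene Trem2 and Tmem119 were among them. The endothelial gene Cldn5 (2.24 ± 0.47), the astrocyte gene Slc7a10 (2.83 ± 0.57) and the pyramidal gene Neurod2 (2.14 ± 0.45) rose too. Itgb5 (4.73 ± 0.71), Ltc4s, Irf1, Slc2a5 and P2ry6 rose as leading genes outside the lists, along with the immunoproteasome subunits Psmb9 and Psmb8. Of 29 rapid activity genes Nr4a1 (2.51 ± 0.36; 67.2 ± 17.3 against 10.6 ± 4.33 CPM), Junb (2.06 ± 0.37), Csrnp1 and Ier2 rose, and over the list alone 12 rose and 1 fell (adjusted p = 0.128 with an estimated correlation). Arc stood at 208 ± 78.8 against 43.0 ± 25.2 CPM (2.17 ± 0.49, adjusted p = 0.0504). Mme, a membrane endopeptidase (-3.56 ± 0.55), Il1rapl2, Matn2, Fbxo3, Pak3 and Exoc3 fell. Parvalbumin neuron genes were lower for 7 of 7 members, median -2.31, and GABA neuron genes for 12 of 12, median -1.64, with 0 passing singly and 6 and 4 over the list alone (adjusted p = 0.277 for both with an estimated correlation). The own-class score fell from 4.40 in home cage to a mean of 0.41 over shock libraries, of which replicate 1 stood at 4.78 and the others between -2.69 and 1.20. The count was 0 with GC and length offsets or the own-class score, 1 with the non-neuronal score, 388 with sex as a covariate, and 0 without the libraries whose own-class score lay less than 1 log2 unit above the lysates. It was 0 without home cage replicate 1 or 2 or shock replicate 2, 4 or 5, 1 without home cage replicate 3, 74 without shock replicate 3, 478 without home cage replicate 4 and 820 without shock replicate 1. Box against home cage gave 0 genes (edgeR; 681 at an unadjusted p under 0.05, 74 by DESeq2) and shock against box 0 (1384 and 325), the latter 134 without shock replicate 1 and 1 with the non-neuronal score. The rapid activity list was higher for 27 of 29 genes in box against home cage, with 5 up over the list alone (list adjusted p = 0.0541).

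At 60 min 732 of 16301 genes differed between shock and home cage in the purified Sst fraction, 382 higher and 350 lower (edgeR; DESeq2 called 1987). With DESeq2's size factors in edgeR 306 were higher and 434 lower. The 4 and 5 libraries did not overlap in 1722 (10.6%) of all genes tested (1.59% by chance). Markers of inhibitory neurons fell: Sst (chromosome 16, 23889573 to 23890958) from 1987 ± 1417 to 69.8 ± 77.5 CPM (-4.93 ± 1.23 SE, adjusted p = 0.0397), Cort (-4.09 ± 0.84), Npy (-3.79 ± 0.86) and Crhbp (-3.48 ± 0.75), 4 of 7 somatostatin neuron genes. Of 12 GABA neuron genes 8 fell, among them Gad2 (-2.69 ± 0.54), Gad1 (-2.13 ± 0.52) and Dlx1 (-2.33 ± 0.35), and Pvalb fell by 2.66 ± 0.65. Sst was near 0 in the lysates of shock replicates 1 and 4 too, at 0.333 and 0.386 CPM, and between 52.8 and 279 CPM in the other Sst lysates at 60 min. The labels name 1 genotype for the whole line and the number of copies of each allele is not given in the sources used here, so whether the Sst fold compares mice of the same genotype is open. The estimated-correlation test gave adjusted p = 0.0978 for the somatostatin and 0.0948 for the GABA neuron list. Genes of other classes rose: 3 of 7 dentate granule cell genes, with Prox1 (1.26 ± 0.28) and C1ql2 (1.20 ± 0.22), and 4 of 12 oligodendrocyte genes, with Mbp (5301 ± 1787 against 2154 ± 658 CPM) and Mobp. So did 2 of 12 astrocyte genes, Aldh1l1 and Gjb6. The dentate list passed with an estimated correlation (adjusted p = 0.0201), the other lists did not (0.0948 for both). Of 20 glucocorticoid genes 18 were higher, 6 rose and 14 over the list alone (adjusted p = 0.00267 with an estimated correlation), with Pdk4 (1.57 ± 0.37), Sgk1 (1.55 ± 0.22; 211 ± 41.8 against 68.5 ± 19.7 CPM), Nfkbia (1.11 ± 0.27) and Fam107a (1.06 ± 0.21). Of 17 circadian genes Per2 (1.11 ± 0.20), Per3 (1.02 ± 0.27) and Bhlhe40 (0.93 ± 0.22) rose (list adjusted p = 0.0456). Rapid activity genes Btg2 (chromosome 1, 134075170 to 134079120; 1.91 ± 0.21), Trib1, Nr4a1 (0.95 ± 0.21) and Nr4a2 rose, 4 of 29 and 8 over the list alone (adjusted p = 0.0778 with an estimated correlation). Fos, Arc, Npas4 and Egr1 did not pass (adjusted p = 0.278, 0.333, 0.474 and 0.789). Of 76 oxidative phosphorylation genes 75 were lower, 15 fell and 53 over the list alone, led by Cox5a (-1.54 ± 0.34) and Ndufa4 (-1.21 ± 0.29; adjusted p = 0.0778 with an estimated correlation). The leading fallen genes were Rgs10 (chromosome 7, 128373621 to 128418758; -2.10 ± 0.19, 38.0 ± 4.64 against 154 ± 31.4 CPM), Dlx2, an interneuron transcription factor (-1.78 ± 0.18), Stmn2, Gpr83, Tmem130 and Bid. The leading risen ones besides Btg2 were Wbp1l, Ikzf4, Fam53b, Rasl10a and Emp2. The own-class score differed between these groups as given above. With it as a covariate 376 genes were called, 115 of them among the 732, with GC and length offsets 1726, with sex as a covariate 359, and without the 3 libraries of over 250000000 counts 138. Single libraries moved the count to 375 without home cage replicate 2, 340 without replicate 4 and 281 without replicate 5, and to 373, 362 and 89 without shock replicates 2, 3 and 4.

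Shock against box in the same libraries gave 1333 genes, 590 higher and 743 lower (edgeR; DESeq2 called 2625), and box against home cage 0 (edgeR; 79 at an unadjusted p under 0.05, 0 by DESeq2). The 4 shock and 4 box libraries did not overlap in 3091 of the 16301 genes tested (2.86% by chance). Inhibitory neuron genes were again lower: Sst at 69.8 ± 77.5 against 2796 ± 1607 CPM (-5.46 ± 1.28 SE, n = 4 each). They were 6 of 7 somatostatin, 9 of 12 GABA and 4 of 7 parvalbumin neuron genes (adjusted p = 0.0716, 0.0701 and 0.159 with an estimated correlation). Fos was lower after shock than after box (-1.20 ± 0.28, 35.2 ± 5.23 against 73.4 ± 9.07 CPM, adjusted p = 0.0252). So were the neuropeptide precursor genes Vgf (-2.20 ± 0.54) and Scg2 (-2.06 ± 0.47). The shock lysates held 35.1 to 48.5 CPM of Fos. Own-class scores differed as given above, so no shift here is assigned to Sst cells. Of 76 oxidative phosphorylation genes 41 fell, 71 over the list alone (list adjusted p = 0.0709). Of 20 glucocorticoid genes 6 rose, 12 up and 1 down over the list alone (list adjusted p = 0.0131). Pdk4 rose by 2.03 ± 0.40 and Sgk1 by 1.24 ± 0.23. Dlx2 (-2.08 ± 0.19), Rgs10 (-2.12 ± 0.20), Gpr83 and Stmn2 led the fallen genes, and Kank1 (2.44 ± 0.30), Emp2, Rbms2 and Dusp18 the risen. Of 7 dentate granule cell genes 4 rose (list adjusted p = 0.0247). The count was 2440 with GC and length offsets, 820 with the non-neuronal score, 329 with the own-class score (92 shared) and 641 without the libraries of over 250000000 counts. It was 686, 709 and 206 without box replicates 1, 3 and 4, and 651 and 237 without shock replicates 2 and 4.

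**Figure D4:**
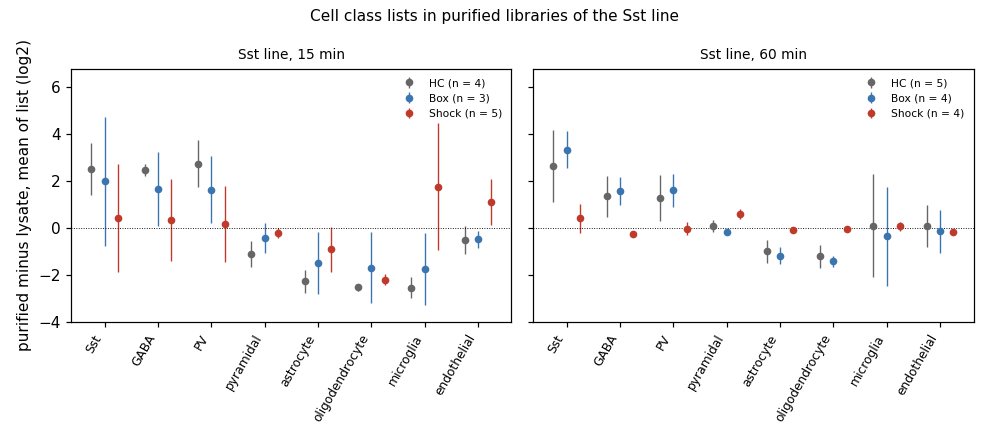
Mean log2 difference of cell class marker lists (y axis) between purified and lysate Sst libraries of the same time set and condition. Points are group means, bars the SD over libraries, and lysate baselines differ. At 60 min the somatostatin list has a mean of 2.66 in home cage, 3.34 in box and 0.41 in shock libraries, and at 15 min the microglia list has -2.55 in home cage and 1.77 in shock libraries.

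To see which shock responses differed between the purified fraction and the lysate, the 2 responses against home cage were subtracted within each table. In the Pvalb line at 60 min 3509 of 17167 genes responded differently, 2232 towards higher and 1277 towards lower values in the purified fraction (edgeR; DESeq2 called 4617, 3347 of them shared). Ribosomal protein genes were among the first, 35 of 80, with Rpl36 (1.55 ± 0.30 SE) and Rpl18 (1.48 ± 0.26). So were 31 of 76 oxidative phosphorylation genes, with Ndufb7 (1.47 ± 0.26), and 6 of 20 ATF4 genes (adjusted p = 0.880 for each of these lists with an estimated correlation). Sh3bp4 (2.12 ± 0.32), Shd (1.86 ± 0.31) and Zfp771 (1.53 ± 0.27) led the higher genes, and Fam8a1 (-1.85 ± 0.33), Prkaa2, the catalytic alpha 2 subunit of AMPK (-1.96 ± 0.35), and Rbm12b2 (-1.82 ± 0.34) the lower ones, all with adjusted p = 0.00231. Arc responded more in the purified fraction (1.05 ± 0.35, adjusted p = 0.0343). GC slope moved with the condition here too, as given for the purified libraries. Leaving out a numbered replicate in both fractions, shock replicate 3 gave 1548 genes, shock replicate 4 gave 1619, shock replicate 5 gave 1825 and home cage replicate 6 gave 2326, while without shock replicate 1 or 2 there were 5581 and 5580. With the replicate number as a block 0 genes were called.

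In the Sst line at 15 min 269 genes responded differently in the purified fraction and the lysate, 239 higher and 30 lower (edgeR; DESeq2 called 1136, all 269 among them). Microglia genes made up the clearest group, 12 of 12 higher with a median of 5.05, 11 past the threshold and 12 over the list alone (adjusted p = 0.0551 with an estimated correlation), C1qa with 5.86 ± 0.95 SE. Slc2a5 (4.50 ± 0.68), Itgb5 (4.38 ± 0.68) and Ptpn6 (5.09 ± 0.82) led the higher genes, and Mme (-3.38 ± 0.60) and Mtmr4 (-1.35 ± 0.26) the lower. The purified libraries also differed in own-class score, as given above. With a replicate left out of both fractions the count was 95, 129 and 86 without home cage replicates 1, 2 and 3, 747 without home cage replicate 4, 810 without shock replicate 1, and 88, 147, 61 and 54 without shock replicates 2, 3, 4 and 5. It was 0 with the replicate number as a block. At 60 min 7 genes responded differently, 5 higher and 2 lower (edgeR; 1753 at an unadjusted p under 0.05, 335 by DESeq2, 6 of them shared). They included Zcchc3 (1.88 ± 0.30), Kank1 (2.0 ± 0.33), Btg2 (1.83 ± 0.32) and Rgs10 (-2.12 ± 0.32). All 76 oxidative phosphorylation genes were lower, median -0.93, 23 of them over the list alone (adjusted p = 0.0273 with an estimated correlation). The somatostatin (median -3.15), GABA (-1.83), oligodendrocyte (1.30) and dentate granule cell (1.19) lists passed in the same way (adjusted p = 0.0368, 0.0271, 0.00764 and 0.00764). Purified shock libraries had low own-class scores here, and the lysates of home cage replicates 4 and 5 had over 250000000 counts and GC slopes of 0.89 and 1.09. Without the libraries of that depth in either fraction 42 genes were called, 5 of the 7 among them, and none of these 5 lists passed (adjusted p = 0.269 for oxidative phosphorylation, then 0.281, 0.281, 0.105 and 0.0741, with an estimated correlation). The 7 calls became 0 without shock replicate 3 or 4, 1 without home cage replicate 2, 3 without home cage replicate 1, 4 or 5 or shock replicate 2, 4 without shock replicate 1, and 52 without home cage replicate 3.

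The other fraction comparisons held 1 gene or none. In the Camk2a line at 15 min it was Zfp54, a zinc finger gene, at 0.00216 ± 0.00432 CPM in shock and 4.03 ± 2.61 in home cage purified libraries (n = 4 and 3; adjusted p = 0.00110; DESeq2 called 77 genes). There the count was 2 without home cage replicate 3, 5 without shock replicate 1, 4 without shock replicate 2 or 3, 3 without shock replicate 4, and 0 with the replicate number as a block. In the Camk2a line at 60 min it was 0 (edgeR; 2376 at an unadjusted p under 0.05, 126 by DESeq2), 1 without home cage replicate 2 or 4 or shock replicate 2 and 2 without shock replicate 4. In the Pvalb line at 15 min it was 0 (edgeR; 1333 at an unadjusted p under 0.05, 242 by DESeq2), and 1 without home cage replicate 4.

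Shock responses of the purified fractions were then compared between lines. At 15 min the Sst line stood apart by its microglia genes. Their list, at a mean of 1.77 over the lysate after shock, reached 2.79 in an unshocked Sst library at 60 min. It does not mark shock alone. All 12 genes were lower in the Camk2a than in the Sst response (median -5.10, 9 past the threshold, 11 over the list alone). So they were in the Pvalb response (median -4.48, 5 and 12). The list had adjusted p = 0.00966 and 0.00350 with an estimated correlation. C1qa stood at 396 ± 264 CPM after shock and 6.04 ± 1.72 in home cage in the Sst line (SD, n = 5 and 4) and at 1.85 ± 0.93 and 2.10 ± 1.03 in the Camk2a line (n = 4 and 3). In all, Camk2a and Sst responses differed in 51 of 16427 genes, 4 higher and 47 lower in Camk2a (edgeR; DESeq2 called 610), among them the integrin gene Itgb5 (-5.77 ± 0.86 SE), Rab3il1 (-3.53 ± 0.61), Gfap (-3.94 ± 0.80) and the activity gene Nr4a1 (-1.75 ± 0.41). Pvalb and Sst responses differed in 13 genes, all lower in Pvalb (DESeq2 called 289), among them Cst3 (-3.18 ± 0.59). Camk2a and Pvalb responses differed in 1 gene, Rtp4, at 1.13 ± 1.27 CPM after shock and 0 in home cage in the Camk2a line and at 2.01 ± 1.46 and 5.07 ± 3.58 in the Pvalb line (edgeR; 899 at an unadjusted p under 0.05, 365 by DESeq2). The 51 became 26, 32, 33, 30 and 28 without Camk2a home cage replicates 1 and 3 and shock replicates 1, 2 and 4, and 17, 31 and 19 without Sst home cage replicates 1, 2 and 3. It became 178 without Sst shock replicate 1, and 32, 21 and 25 without Sst shock replicates 2, 4 and 5. The 13 became 125 without Sst shock replicate 1, 5 without Pvalb home cage replicate 2, 4 without Pvalb home cage replicate 3 or Sst shock replicate 3, 3 without Pvalb shock replicate 3, 1 without Sst home cage replicate 4 and 0 without any other single library. The 1 gene became 0 without Camk2a home cage replicate 1 or 3, 4 without its home cage replicate 2 or shock replicate 1, 3 without its shock replicate 2, and 2 without its shock replicate 3 or 4 or Pvalb shock replicate 1.

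At 60 min the lines differed more widely. Camk2a and Pvalb responses differed in 6508 of 17325 genes, 2903 higher and 3605 lower in Camk2a (edgeR; DESeq2 called 7314). Ribosomal protein genes were lower in the Camk2a response in 40 of 80 cases and higher in 5, with Rps4l (-2.20 ± 0.39 SE) and Rpl36 (-2.13 ± 0.38). Oxidative phosphorylation genes were lower in 36 of 76 and higher in 15, with Ndufs7 (-2.02 ± 0.33). Of 20 ATF4 genes 10 were lower and 2 higher, and of 16 GABA receptor genes 8 were higher, with Gabra2 (1.75 ± 0.54), and 3 lower, with Gabrd (-1.66 ± 0.33). All 4 lists had adjusted p = 0.913. Of 25 delayed activity genes 11 were higher and 4 lower, Tiparp by 2.16 ± 0.44 (adjusted p = 0.291 with an estimated correlation). Arc was lower in Camk2a (-1.16 ± 0.41, adjusted p = 0.0261) and Bdnf higher (0.82 ± 0.32, adjusted p = 0.0426). By rank Nup88 (1.14 ± 0.19), Pcdhb10 and Sgk3 led the higher genes, and Rhbdd3 (-2.78 ± 0.32, adjusted p = 1.79e-06) and Dnajc4 (-2.13 ± 0.28) the lower. GC slope moved in opposite directions in these lines, as given above. Camk2a and Sst responses differed in 841 genes, 516 higher and 325 lower in Camk2a (edgeR; DESeq2 called 1625). Somatostatin neuron genes were among the higher, 4 of 7, with Sst (4.83 ± 0.99) and Npy (4.01 ± 0.73). So were 7 of 21 neuropeptide genes and 4 of 25 delayed activity genes, with Scg2 (2.21 ± 0.42), Rgs2 (2.04 ± 0.33) and Vgf (2.0 ± 0.51). Oligodendrocyte genes were lower in 5 of 12 cases and astrocyte genes in 3 of 12, with Aldoc (-1.82 ± 0.33). With an estimated correlation these lists passed, at adjusted p = 0.0396 for the somatostatin, oligodendrocyte and astrocyte, 0.0222 for the neuropeptide and 0.0161 for the delayed activity list. Pvalb and Sst responses differed in 3152 genes, 2338 higher and 814 lower in Pvalb (edgeR; DESeq2 called 3715). These included Sst (6.01 ± 0.95), Cort (5.43 ± 0.73), Cgref1 (3.04 ± 0.37) and Vgf (2.65 ± 0.48) higher and Dusp18 (-1.96 ± 0.29), Sgk1 (-1.25 ± 0.29) and Gja1 (-1.92 ± 0.49) lower. There 50 of 76 oxidative phosphorylation and 36 of 80 ribosomal protein genes were higher (list adjusted p = 0.0997 and 0.418). The own-class score of the Sst shock libraries, given above, goes with both Sst comparisons. The 841 became 511, 503, 511, 485 and 543 without Sst home cage replicates 2 and 4 and shock replicates 1, 3 and 4, 1570 without Sst shock replicate 2, and 1299 and 1514 without Camk2a shock replicates 2 and 3. The 3152 became 2057 without Sst shock replicate 2.

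The shock responses of the 60 min and 15 min sets were compared within each line. In the Camk2a line 856 of 14979 genes differed, 163 with a higher and 693 with a lower response at 60 min (edgeR; DESeq2 called 1811, 538 higher and 1273 lower). Arc had the lower response at 60 min (-2.05 ± 0.48 SE, adjusted p = 0.0214). It stood at 305 ± 168 CPM after shock and 76.2 ± 20.9 in home cage in the 15 min set (SD, n = 4 and 3), and at 400 ± 243 and 413 ± 61.9 in the 60 min set (n = 5 and 4). Ier2 (-3.31 ± 0.68) and the phosphatase gene Dusp1 (-1.95 ± 0.49) had lower and Fosl2 (1.38 ± 0.41) a higher response. Of 29 rapid activity genes 8 lay higher, and 3 were lower past the threshold and 7 over the list alone, with 1 higher in each count (adjusted p = 0.759 with an estimated correlation). Of 79 ribosomal protein genes 12 were lower, Rpl36 by -2.56 ± 0.59, and 11 of 76 oxidative phosphorylation genes, Ndufs7 by -1.88 ± 0.37 (adjusted p = 0.759 and 0.766 with an estimated correlation). By rank Fam98c (-2.73 ± 0.41), Mcrs1 and Plbd2 led the lower genes, and Prkab2 (1.90 ± 0.35), Suco and Ccny the higher. GC slope moved in opposite directions in these sets, from -0.09 in home cage to 0.21 in shock libraries at 15 min and from 0.22 to -0.25 at 60 min. The count was 1, 160, 348, 1753 and 149 without home cage replicates 1, 2 and 3 and shock replicates 1 and 4 of the 15 min set. It was 143, 320, 1399 and 339 without home cage replicate 1 and shock replicates 1, 3 and 4 of the 60 min set. In the Pvalb line 0 genes differed (edgeR; 1531 at an unadjusted p under 0.05, 264 by DESeq2), with 1 without home cage replicate 4 at 15 min or shock replicate 2 at 60 min. In the Sst line 0 differed (2653 and 700), with 2, 84, 144 and 1 without home cage replicates 1 and 4 and shock replicates 1 and 2 at 15 min. Rapid activity genes lay lower at 60 min in both, with medians of -0.60 and -0.59, and over the list alone 2 and 6 were lower (list adjusted p = 0.460 and 0.610).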

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

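Tests chosen only after the result was seen were all those on the Sst and Pvalb patterns below and the splits of purified Camk2a and Pvalb libraries, and for purified Camk2a libraries at 60 min the number of genes called under both corrections was known when the tests were chosen.

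Own-class scores were low in all 4 purified Sst libraries of shocked mice at 60 min (-0.51 to 0.01), in home cage replicate 3 there (-0.24) and in box replicate 2 at 15 min (-0.62), and at 15 min shock libraries had -2.69 to 1.20 apart from replicate 1 (4.78), where the score also subtracts the microglia list, at a mean of 1.77 over the lysate. A change within Sst cells after shock stays open and untested, since the GABA neuron list, at -0.28 ± 0.10 log2 units over the lysate in shock libraries at 60 min (SD, n = 4) and 0.34 ± 1.74 at 15 min (n = 5), is itself part of that score. A purified fraction close to the whole lysate stays open at 60 min: the farthest list, of pyramidal genes, had a median of 1.18, past the bound of 1 first set for this test but by less than its SE over members (0.33), a margin required only after the value had been seen. A missing tagged ribosomal protein stays open too: Rpl10a, whose sequence such a tag carries, stood over other large subunit genes by 0.84 more in purified than in lysate home cage libraries and by 0.19 in shock libraries at 60 min, but by -0.06 in home cage libraries of both other lines at 60 min and by -0.12 in home cage and 0.48 in shock libraries of the Sst line at 15 min, so the lack of a rise does not mark a missing tag. Microglia RNA in the purified fraction at 15 min is open as well, since the 12 of 12 microglia genes higher after shock than in home cage also prompted this explanation and do not test it, and single unshocked libraries at 60 min held the list as high (up to 2.60 over the lysate in home cage and 2.79 in box, with a mean of 0.07 in shock).

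In purified Pvalb libraries at 60 min 5655 genes differed between shock and home cage. GC content or gene length bias as the whole cause is argued against by the 2002 genes called with per-library offsets, 1588 of them among the 5655. A batch within the shock group stays open: shock replicates 1 and 2 showed 0.343 and 0.270 of the change of replicates 3 to 6 over the 7947 genes these gave alone, and single box libraries showed 0.0504 to 0.588 of it. The labels give no batch, so for replicates 3 to 6 a batch and the response to shock cannot be told apart. The response to shock, which the design names, stays open as well.

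In purified Camk2a libraries at 60 min 338 genes differed between shock and home cage. Sex as the cause is argued against: the covariate left 0.958 of their median log2 change (0.88 before, 0.85 after), and 0 were called as the median SE rose from 0.20 to 0.24 and adjusted p-values had been close to the threshold before, with the part of each in the loss not tested. GC and length offsets left 0.585 of it (0.52 after, median SE 0.17, the same sign in 336 of 338), and 1 gene was called. Part of the pattern may therefore come from GC content or gene length. The rest cannot be told apart from an effect of shock on the values at hand.

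Each count of genes was set against the counts of other splits of the same libraries, the real one included. Chance can be excluded for shock against home cage in purified Camk2a at 60 min, where 2 of 100 splits gave as many as the real 338 (highest other 1551), in Pvalb at 60 min (1 of 100, real 5655, highest other 4061), in Sst at 15 min (3 of 100, real 194, highest other 875) and in Sst at 60 min (3 of 100, real 732, highest other 2511). With the replicate block the 194 became 0 and the 732 fell. In 15 min lysates the share was 1 of 40 for shock against home cage (real 20, highest other 1). It was so for box (real 2, highest other 0). The Sst fraction difference had 1 of 40 at 15 min (real 269, highest other 175), but 0 genes with the number as a block over both fractions. At 60 min it had 1 of 40 too (real 7, highest other 0). For the time difference in Camk2a the share was 1 of 40 (real 856, highest other 343). Between lines it was 1 of 25 for Camk2a and Sst at 15 min (real 51, highest other 3). At 60 min it was 1 of 25 for Camk2a and Pvalb (real 6508, highest other 41). It was so for Camk2a and Sst (real 841, highest other 184) and Pvalb and Sst (real 3152, highest other 1).

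The share was 0.05 or more for shock against box in Sst at 60 min (2 of 35, real 1333, highest other 1430). It was so for the fraction difference in Pvalb at 60 min (2 of 40, real 3509, highest other 4576). For that in Camk2a at 15 min it was 21 of 40 (real 1, highest other 3), and both differences were 0 with the block. Between lines at 15 min it was 11 of 25 for Camk2a and Pvalb (real 1, highest other 3). For Pvalb and Sst it was 2 of 25 (real 13, highest other 66). Where the real edgeR count was 0 (counts at an unadjusted p and by DESeq2 stand with each comparison) every split gave as many, and the highest others were, for shock against home cage, box against home cage and shock against box, 72, 0 and 119 in Camk2a at 15 min (35, 10 and 35 splits) and 1115, 7 and 1815 in Pvalb at 15 min (100, 35 and 100). The 10 splits are too few for a share under 0.05. For box against home cage and shock against box they were 0 and 369 in Camk2a at 60 min (35 and 56), 1 and 5885 in Pvalb at 60 min (100 each) and 1 and 452 in Sst at 15 min (35 and 56). Box against home cage in Sst at 60 min reached 3219 (100). In lysates shock against box reached 539 at 15 min, and at 60 min the 3 contrasts reached 0, 6112 and 0 (40 each). The fraction difference reached 2823 in Camk2a at 60 min and 321 in Pvalb at 15 min, and the time difference 1 in Pvalb and 3 in Sst (40 each). The median of the other splits was 0 in each of these. Single splits with many times the real count, such as the 6112, 5885 and 3219, or the 1551, 875 and 2511 beside the real 338, 194 and 732 above, point to a structure of the samples other than the condition.

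The test of the difference between responses called the following numbers of genes, of which chance cannot be excluded for the 3509, the 13 and both counts of 1. Between fractions they were 1 in Camk2a at 15 min, 3509 in Pvalb at 60 min, and 269 and 7 in Sst at 15 and 60 min. Between lines they were 1 for Camk2a and Pvalb, 51 for Camk2a and Sst and 13 for Pvalb and Sst at 15 min, and 6508, 841 and 3152 at 60 min. Between time sets 856 genes differed in Camk2a.

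In 30 of 230 pairs of group and activity gene, marker or score, 1 library lay far out. Chance gives 11.5 for independent tests, which these are not. In the Camk2a set at 15 min, shock replicate 4 held 462 CPM of Fos, 734 of Arc, 179 of Npas4 and 622 of Egr1 in the lysate, where the other 3 held at most 46.6, 218, 6.29 and 245. Its purified fraction held 353 CPM of Fos and 83.4 of Npas4, against at most 44.0 and 4.58 in the others. In Camk2a at 60 min the purified fraction of shock replicate 3 held 820 CPM of Arc and its lysate 19.5 of Npas4, purified home cage replicate 2 held 13.5 of Pvalb, and purified shock replicate 5 held 109 of Sst. In Pvalb at 60 min the lysate of box replicate 4 held 43.3 CPM of Fos and 563 of Arc. Purified home cage replicate 6 held 82.4 of Arc, purified shock replicate 1 held 149 of Egr1, purified home cage replicate 3 held 447 of Camk2a, and purified box replicate 2 had an own-class score of 5.13. In Sst at 15 min shock replicate 1 held 70.4 CPM of Fos and 78.5 of Bdnf in the lysate, the latter the lowest of its group, and 123 of Fos and 3745 of Sst in the purified fraction. There the lysate of shock replicate 4 had the lowest Egr1 (380), lysates of home cage replicate 2 and shock replicate 5 held 279.1 and 278.7 of Sst, the former also 1347 of Camk2a, and purified home cage replicate 3 held 1.04 of Npas4. In Sst at 60 min the lysates of shock replicates 1 and 2 held 48.5 of Fos and 2.27 of Npas4, that of box replicate 1 held 10.3 of Npas4 and 1264 of Camk2a, and purified home cage replicate 5 held 6.26 of Npas4.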

How the results depend on the processing

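Tests chosen only after the results had been seen were those with GC and length offsets, with the own-class score or sex as a covariate, and without libraries of low own-class score, libraries of over 250000000 counts or part of the Pvalb shock libraries at 60 min. Over all settings 511 counts of genes, counts of lists and medians stayed within 1.5 times the reported count or within the spread, 218 counts were lower than that, 121 were higher and 1 median moved. Of the log2 fold changes of named genes 3789 kept their side of the threshold. Any change of sign in genes past the threshold in neither fit is counted among these. Another 1083 kept the direction and no longer passed, 19 passed newly, and 2 changed sign while past the threshold in at least 1 fit. The 2 were Gria2 in purified Camk2a libraries at 60 min (-0.044) and Egr4 in purified Pvalb libraries at 60 min (-0.19), both with GC and length offsets, which by construction take out each library's trend over GC content and over length together. Which of the 2 moved these genes was not tested. For the other changes below the cause was not tested either, apart from the smaller number of libraries where some were left out. Simulated 2-fold changes were recovered least in the purified Sst and Pvalb sets at 15 min (1.03% and 5.26%), and how much of this limit is due to depth and how much to spread was not tested.

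DESeq2 called more genes than edgeR in most comparisons. For shock against home cage, box against home cage and shock against box in purified libraries, it called 81, 40 and 37 for Camk2a at 15 min, 2133, 16 and 105 at 60 min, and 390, 67 and 530 for Pvalb at 15 min. It called 42 for box against home cage and 653 for shock against box for Pvalb at 60 min. For Sst it called 1855, 74 and 325 at 15 min, and 1987 for shock against home cage and 2625 for shock against box at 60 min. In lysates it called 68, 61 and 17 at 15 min and 22, 16 and 19 at 60 min. For the fraction differences it called 77 and 126 in Camk2a at 15 and 60 min, 242 in Pvalb at 15 min, and 1136 and 335 in Sst. Between lines at 15 min it called 365 for Camk2a and Pvalb, 610 for Camk2a and Sst and 289 for Pvalb and Sst, and 1625 for Camk2a and Sst at 60 min. Between time sets it called 1811, 264 and 700 for Camk2a, Pvalb and Sst.

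DESeq2's size factors in edgeR gave 181 genes for purified Camk2a libraries at 60 min and 4 for the fraction difference in Sst at 60 min. Without a filter on low counts that difference held 4 genes and the difference of Pvalb and Sst at 15 min held 4. GC and length offsets gave 2 genes for shock against home cage in lysates at 60 min, 1 in purified Camk2a at 60 min, 2002 in Pvalb at 60 min, 0 in Sst at 15 min and 1726 in Sst at 60 min, and 2440 there for shock against box. The non-neuronal score gave 0 in Camk2a at 60 min, 6 in Pvalb at 15 min and 1 in Sst at 15 min, and for shock against box 281 in Pvalb at 60 min, 1 in Sst at 15 min and 820 in Sst at 60 min. The own-class score gave 0, 3, 0 and 376 for shock against home cage in Camk2a at 60 min, Pvalb at 15 min, Sst at 15 min and Sst at 60 min, and 1 and 329 for shock against box in Pvalb and Sst at 60 min. Sex gave 0 in Camk2a at 60 min, 388 in Sst at 15 min and 359 in Sst at 60 min. Without libraries of low own-class score the count for Sst at 15 min was 0. Without libraries of over 250000000 counts it was 1 for lysates at 60 min, 138 for Sst at 60 min, 641 there for shock against box and 42 for the fraction difference. In Pvalb at 60 min, shock replicates 3 to 6 alone gave 404 for box against home cage and 5014 for shock against box, and shock replicates 1 and 2 alone gave 0 for shock against home cage. In lysates at 15 min, box against home cage gave 7 without the Camk2a, 0 without the Pvalb and 0 without the Sst line, and shock against home cage 2 without Pvalb and 2 without Sst. In home cage libraries alone the parvalbumin list in purified Pvalb libraries at 60 min had a median of 3.98.

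By the correlation of deviations from group means, in no table did every pair of 1 number exceed 0.1, over fractions or over conditions. Of 72 purified libraries 46 correlated best with the lysate of their own number and 66 matched it in sex, a hint that a number marks 1 animal in both fractions. These were 10 and 10 of 10 in Camk2a at 15 min, 9 and 11 of 12 at 60 min, 10 and 11 of 11 and 6 and 10 of 14 in Pvalb, and 7 and 11 of 12 and 4 and 13 of 13 in Sst. Titles name both fractions of a number alike, but fraction differences were fitted and split as if independent, so block counts stand beside them. With the replicate block, the fraction difference held 0 genes in Camk2a at 15 min, 0 in Pvalb at 60 min and 0 in Sst at 15 min. Shock against home cage held 12 and box against home cage 10 in lysates at 15 min, and shock against home cage 3678 in Pvalb at 60 min, 0 in Sst at 15 min and 8 in Sst at 60 min, with 1 for shock against box in Pvalb at 60 min. Lists called with the block numbered 0 for the fraction difference in Camk2a and for shock against box in Camk2a at 60 min, 3 for shock against box in Pvalb at 15 min and 1 for box against home cage in Pvalb at 60 min. The block moved no other count of genes or lists by over 1.5 times, and of the medians only that of the somatostatin list in purified Sst libraries at 15 min (1.95).

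Leaving out 1 library, or 1 number in both fractions, gave these ranges of gene counts. The fraction difference ran from 1 to 5 and 0 to 2 in Camk2a at 15 and 60 min, 0 to 1 and 1548 to 5581 in Pvalb, and 54 to 810 and 0 to 52 in Sst. Between lines it was 0 to 4 and 5597 to 7155 for Camk2a and Pvalb at 15 and 60 min, 17 to 178 and 485 to 1570 for Camk2a and Sst, and 0 to 125 and 2057 to 3682 for Pvalb and Sst. Between time sets it was 1 to 1753, 0 to 1 and 0 to 144 for Camk2a, Pvalb and Sst. For shock against home cage it was 0 to 3 and 0 to 1858 in Camk2a at 15 and 60 min, 0 to 6 and 4289 to 6828 in Pvalb, and 0 to 820 and 89 to 831 in Sst. For shock against box it was 0 to 1419 in Pvalb at 60 min and 0 to 134 and 206 to 1182 in Sst at 15 and 60 min. In the other purified contrasts it was 0 throughout.

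Of the 19 lists tested in each comparison, those called are given for camera, then for camera with an estimated correlation, fry for 1 direction and fry for either direction. For the purified fraction over the lysate (Camk2a at 15 and 60 min, Pvalb, then Sst) camera called 8, 11, 6, 7, 6 and 5. With the others the counts were 2, 1, 1, 1, 3 and 0, then 15, 18, 15, 18, 12 and 16, then 19, 19, 19, 19, 19 and 19. For the fraction differences in the same order camera called 2, 1, 2, 3, 4 and 10. The other tests called 0, 0, 0, 0, 0 and 2, then 0, 0, 0, 4, 0 and 6, then 0, 0, 0, 16, 9 and 3. For the line differences (Camk2a and Pvalb at 15 and 60 min, Camk2a and Sst, then Pvalb and Sst) camera called 4, 4, 5, 11, 1 and 6. With the others the counts were 0, 0, 0, 2, 0 and 0, then 0, 8, 2, 7, 0 and 8, then 0, 16, 0, 11, 0 and 15. For the time differences (Camk2a, Pvalb, then Sst) camera called 2, 5 and 6. The other tests called 0, 0 and 0, then 1, 0 and 0, then 19, 0 and 3. For lysates (shock against home cage, box against home cage and shock against box at 15 min, then at 60 min) camera called 6, 5, 4, 5, 6 and 2. With the others the counts were 2, 1, 1, 3, 3 and 0, then 2, 1, 0, 3, 0 and 0, then 3, 1, 0, 0, 0 and 0. For purified Camk2a libraries in the same order camera called 3, 5, 3, 5, 3 and 1. The other tests called 0, 1, 0, 0, 0 and 0, then 0, 1, 1, 5, 1 and 0, then 0, 0, 0, 17, 0 and 5. For purified Pvalb libraries camera called 4, 2, 1, 4, 0 and 7. With the others the counts were 0, 0, 0, 0, 0 and 0, then 1, 0, 0, 7, 0 and 2, then 11, 0, 10, 19, 0 and 16. For purified Sst libraries camera called 4, 8, 2, 10, 7 and 7. The other tests called 0, 0, 0, 3, 1 and 1, then 1, 0, 0, 9, 0 and 9, then 17, 1, 0, 15, 0 and 15.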

Other observations

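No tests here were chosen only after the result was seen, but which gene lists and single libraries to give was.

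Genes of energy metabolism and ribosomes were compared between the purified fraction and the lysate. Of 76 nuclear genes of oxidative phosphorylation, which encode the respiratory chain and ATP synthase, 70 were higher in purified Camk2a libraries at 15 min past the threshold (median log2 fold 1.33), 70 at 60 min (1.13, with 1 lower), 74 and 76 in Pvalb at 15 and 60 min (1.23 and 1.30), and 75 in Sst at 15 min (1.58). The list passed with an estimated correlation in Camk2a at 15 min (adjusted p = 0.00082), Pvalb at 60 min (0.000847) and Sst at 15 min (0.0297), and not in Camk2a at 60 min (0.0543) or Pvalb at 15 min (0.108). In Sst at 60 min 50 genes were higher and 8 lower (list adjusted p = 0.644). Ribosomal protein genes were higher in 74 of 78 cases in Camk2a at 15 min (median 1.45, adjusted p = 0.0365 with an estimated correlation) and in 78 of 80 in Sst at 15 min (1.47, 0.0230, with 1 lower), and in 53 of 80 in Pvalb at 60 min (0.53, with 4 lower), where the list did not pass (adjusted p = 0.307 with an estimated correlation). Nor did it pass in Camk2a at 60 min (76 of 80 higher, median 1.20), Pvalb at 15 min (67, 0.66) or Sst at 60 min (65, with 3 lower, 0.82), with adjusted p = 0.166, 0.123 and 0.644. Cholesterol synthesis genes went the other way in Pvalb libraries, 13 of 21 lower and 1 higher at 60 min (median -0.54, list adjusted p = 0.216).

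In the Sst set at 60 min the Sst transcript was at 0.333 and 0.386 CPM in the lysates of shock replicates 1 and 4, and at 2.98 and 5.28 CPM in the purified libraries of the same numbers. Npy, a peptide gene of many of the same cells, stood at 125 and 91.5 CPM in these lysates and between 88.3 and 225 CPM in the others of the set. The 3 lysates of over 250000000 counts, home cage replicates 4 and 5 and box replicate 1, held 1183, 1243 and 1264 CPM of Camk2a, where the other 10 lysates of the set held 211 to 449. Their GC slopes were 0.89, 1.09 and 1.04, and those of the other lysates ran from -0.67 to 0.50.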
